A study of Saccharomyces cerevisiae with 36 samples.

How the data were processed

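The samples are RNA from cultures of the yeast Saccharomyces cerevisiae, compared on dual-channel DNA microarrays, 36 arrays in all. Per the labels' protocols, cells grew in YPD, a rich medium, at 30 °C to log phase and received ethanol to 5% by volume. RNA was taken with hot phenol and labelled indirectly with a pair of Oyster dyes, and the arrays numbered 2 carry the dyes the other way round. The series description states biological triplicates for the single time points and a single replicate for the time course, which gives 9 groups of 3 arrays and 9 time-course arrays.

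The authors deposited a table with 1 value per open reading frame and array, read here as the log2 ratio of the array's channels. That unit comes from the values, which take both signs with array medians near 0, because the labels state neither the unit nor the base of the logarithm. Dye-exchanged arrays correlated positively with the other arrays of their group, so the deposited ratios had already been turned to 1 direction per group. The normalisation, the background correction and any filter on spots are not given in the sources used here. The table holds 6295 open reading frames, of which 5830 matched an annotated gene and 465 did not. There are 4981 to 6093 values per array, 2806 open reading frames with a value on all arrays, and 89.1% of all possible values present. No intensities were used, so the number of arrays limits the precision. Array medians ran from -0.08 to 0.17, and 0 pairs of arrays were identical. Pearson correlations between replicate arrays, across genes, were 0.805 to 0.947 in the ethanol groups apart from the array treated below, 0.868 to 0.967 for M22 over DBY8268, 0.674 to 0.813 for YPS163 over DBY8268 and 0.184 to 0.645 for hap1D over YPS163 MATa.

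The titles order the conditions in ways that differ between groups and state no numerator, so the direction of each ratio was settled from the values, after these had been seen, and is likely but not certain. Ethanol ratios are read as ethanol over unstressed cells: the 59 genes above 3.5 lacked a value on 19.8% of log-phase spots, against 1.4% for the 191 genes below -2. The log-phase ratios of the wild strains are read as wild strain over DBY8268: the 77 genes below -4 in M22 lacked a value on 25.1% of M22 ethanol spots against 0.2% of DBY8268 ethanol spots, and the 85 genes below -4 in YPS163 on 27.1% against 0.2%. The hap1D ratios in log phase were turned to hap1D over YPS163 MATa because HAP1 itself then lies at -3.47 ± 0.61 (SD, n = 2).

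Ethanol array 3 of YPS163 MATa was treated as missing. As deposited its column correlated at 0.164 with the mean of the other arrays of its group, and at 0.747 once its values were moved up by 1 position in the table. All 32 blocks of 200 positions correlated best at that offset, and 0 of the other 35 arrays correlated best away from their deposited position. Genes with a strong and repeatable change were taken from 5 other arrays, arrays 1 and 2 of YPS163 MATa and the 3 hap1D ethanol arrays. Their mean was at least 2 in size, with an SD of at most 0.5. Of these genes, 48 of 182 lay within 1.5 of that mean as deposited and 165 of 183 after the move. No other array was held to this limit, so these counts do not show how complete the repair is, and the move was not taken as a full one. This choice was made after its effect on the counts had been seen, and the fit planned for 27 arrays used 26. The counts with the column as deposited and with the column moved are given beside each YPS163 MATa result.

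The comparisons, tests, gene lists, alternatives and rule for naming genes were chosen before the data were examined, except where stated otherwise. In limma 3.58.1 under R 4.3.3, lmFit fitted 1 mean per group to the 26 arrays, with the spread of each gene shared by all groups and moderated by eBayes. A gene was tested in a contrast when it had a value on at least 2 arrays in each group. Benjamini-Hochberg adjustment ran over the genes of each of 15 contrasts, and an adjusted p under 0.05 was a call. Errors beside a group mean are the SD of its arrays, and errors beside a difference of groups are the standard error from the fit. On simulated data with known changes, the share of changed genes called at 1.5-fold, 2-fold and 4-fold was 47.8%, 85.1% and 100% for the ethanol response of DBY8268, with 10 false calls among 165. It was 20.9%, 68.7% and 97% for M22 minus DBY8268 (9 of 133 false) and 11.9%, 68.7% and 90.9% for msn2D minus YPS163 MATa (7 of 121 false). The simulated noise was independent between arrays, and only genes with a value on all arrays were changed. These shares may therefore not hold for the real arrays, where same-numbered arrays deviate together and many genes lack values.

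The 21 gene lists were ribosomal proteins, ribosome biogenesis, general stress (Msn2/4-type) genes, heat shock (Hsf1-type) chaperones, trehalose and glycogen metabolism, ergosterol biosynthesis, Hap1-type targets, respiratory chain and ATP synthase, TCA cycle and glyoxylate, iron regulon, phosphate regulon, cell wall and flocculation, haploid and mating-type genes, amino acid biosynthesis, sulfur and methionine, fatty acid and sphingolipid synthesis, alcohol and acetate metabolism, glucose transport, pleiotropic drug response, proteasome, and genes variable between yeast strains. They were written from general knowledge, and 5 of their names were not used, 3 that found no match and 2 that repeated another member. General stress shares 10 genes with trehalose and glycogen metabolism and 4 with heat shock, and Hap1-type targets share 6 each with ergosterol biosynthesis and the respiratory chain. Each list was tested by limma's cameraPR with a preset correlation of 0.01 and with the correlation estimated from the residuals of genes with complete values, with Benjamini-Hochberg adjustment over 21 lists times 15 contrasts, 315 tests. The fry test of limma asked whether a list's genes with complete values moved, on balance, in 1 direction.

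Genes are named by a fixed rule. It takes the 8 largest rises and 8 largest falls per contrast, not all of which are printed, among called genes with a standard name and the same sign on all measured arrays, or no overlap between the arrays of the groups compared. From each list described it takes up to 3 called members with the largest changes, and the largest against the list. A fixed set counts among the named genes of every contrast: HAP1, MSN2, MSN4, EDE1, ELO1, MGA2, ROX1, CTT1, HSP12, CYC1, CYC7, FLO8, AQY1, AQY2 and ENA1. The time course, with 1 array per strain and time, was not tested; each list is described by its median and by the percentile of that median among 10000 random lists of the same size.

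Arrays with the same number deviated together from their group means in DBY8268, M22 and YPS163, with correlations of 0.237 to 0.596 across genes, all over 0.1, so the numbers pair these arrays. The main fit was planned without a replicate block, so its errors leave this pairing out. On the ethanol arrays of these strains alone, a block raised the count of each contrast between them, as given under the processing settings. Arrays 1 and 3, which share a dye orientation, correlated between strains at -0.158 to -0.491, so the dye exchange on arrays 2 is not the whole of this pairing. Between hap1D and YPS163 MATa the same-numbered arrays 1 and 2 correlated at 0.626 and 0.467, and those arrays crossed at -0.634 and -0.498, which points to a pairing. With 2 YPS163 MATa arrays left, their deviations mirror each other, so these values are not independent. Between msn2D and YPS163 MATa the same-numbered values were -0.234 and -0.038 and settled no pairing. The alternatives tried were array centring, array scaling (limma's normalizeMedianAbsValues), genes present on all arrays, a dye term, a fit of each contrast alone, robust empirical Bayes, an adjusted p under 0.01, a minimum change of 1.5-fold by limma's treat, leaving out each array, and a replicate block. Added after the data were seen were the other treatments of the displaced column and other references for msn2D. The plots were drawn with Python 3.11.15 and matplotlib 3.10.9.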

Results

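Transcript levels were compared within arrays in Saccharomyces cerevisiae before and after 30 min in 5% ethanol, and between strains in log phase without ethanol. DBY8268 is the laboratory reference strain of the S288c background, and M22 and YPS163 are non-laboratory strains, called wild strains here. The ethanol response was measured on 3 arrays each in these strains, in YPS163 MATa, a haploid of mating type a, and in the mutants hap1D and msn2D of the YPS163 background, read from their names as lacking HAP1 and MSN2. Log-phase arrays, 3 per comparison, set M22 and YPS163 against DBY8268 and hap1D against YPS163 MATa. A time course added 1 array per strain at 15, 45 and 60 min for DBY8268, M22 and YPS163. Arrays carried 4981 to 6093 values, and the number of arrays limits the precision. YPS163 MATa counts as n = 2 for ethanol, because its array 3, whose values appear to sit 1 position out of place, was left out. The direction of each ratio and its base of 2 are readings of the values, not statements of the labels. A gene is said to rise, fall or differ only where it passed an adjusted p of 0.05 in limma, and errors are the SD of the arrays for a response and the standard error for a difference. In a difference between strains, higher and lower refer to the signed log2 ratio, so a gene that fell less counts as higher. Each response is taken against the strain's own unstressed level, so a difference of responses is not a difference of levels in ethanol.

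Does ethanol change the transcripts of the laboratory strain? In DBY8268, HSP26, a small heat shock protein gene, rose by a log2 ratio of 9.21 ± 0.87 (SD, n = 3), which is 594-fold. The other largest rises were RGI1 by 8.09 ± 0.38, HSP12 by 7.44 ± 0.55, GPM2 by 7.11 ± 0.72, the Hsp70 gene SSA4 by 6.77 ± 1.21, TMA10 by 6.65 ± 0.51, HSP30 by 6.47 ± 0.45 and HSP42 by 6.33 ± 0.74. URA1, which encodes dihydroorotate dehydrogenase, stood at -3.30 ± 0.32, the nucleolar gene NSR1 at -3.28 ± 0.53, TOD6 at -3.14 ± 0.20, SYO1 at -3.05 ± 0.21, AQR1 at -3.02 ± 0.37, DBP2 at -3.02 ± 0.27 and PHO3 at -3.01 ± 0.24. The catalase gene CTT1 rose by 1.99 ± 0.48 and CYC7 by 2.14 ± 0.65, the aquaporin gene AQY2 changed by -0.55 ± 0.32, and EDE1 at 0.05 did not pass (adjusted p = 0.793). Of 5632 genes tested, 3363 changed, 1613 up and 1750 down, and 1646 of them by at least 2-fold.

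By function, all 83 measured ribosome biogenesis genes fell in DBY8268, with a median of -2.29 and NOG1 at -2.99 ± 0.05, and so did all 127 measured ribosomal protein genes, with a median of -1.80 and RPL7A at -2.49 ± 0.03. Those counts were the same adjusted over the list alone. The camera test gave adjusted p = 1.01e-43 for ribosome biogenesis, 0.0192 with an estimated correlation, and adjusted p = 4.63e-21 for ribosomal proteins, 0.441 with an estimated correlation. General stress genes had 52 up and 4 not passing of 56 (52 up and 1 down adjusted over the list alone), with a median of 2.64 and adjusted p = 7.22e-06 with an estimated correlation. Heat shock chaperones had 27 up and 1 not passing (27 up adjusted over the list alone), with a median of 2.82 and adjusted p = 1.53e-05 with an estimated correlation. Trehalose and glycogen genes had 16 up, 1 down and 2 not passing, among them PGM2 at 5.68 ± 0.37 and TSL1 at 5.40 up and PGM1 at -1.26 down, with adjusted p = 0.0277 with an estimated correlation. The phosphate regulon had 13 down, 2 up and 3 not passing (14 down adjusted over the list alone), PHO84 at -2.98 and PHM8 at 4.07 among them, with adjusted p = 0.0203 with an estimated correlation. On genes with complete values, fry gave adjusted p = 7.04e-11 for ribosome biogenesis and 5.91e-14 for general stress.

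Other lists in DBY8268 were called by camera only at the preset correlation, or not at all. Ergosterol genes had 17 down, 1 up and 10 not passing, with ERG11 at -2.53 ± 0.12, ERG5 at -2.40 and ERG28 at 0.42 (adjusted p = 1.42e-05, and 0.335 with an estimated correlation). Amino acid biosynthesis had 32 down, 5 up and 6 not passing, with ILV5 at -2.47, MET6 at -2.39 ± 0.39 and ARG4 at 1.40 (1.34e-07, and 0.253 with an estimated correlation). The respiratory chain had 25 up, 2 down and 14 not passing, with COX5B at 2.96 and CYB2 at 2.04 ± 0.21 (0.0108, and 0.714 with an estimated correlation). The proteasome had 22 up and 7 not passing (24 up adjusted over the list alone), with RPN4 at 1.69 ± 0.14 (0.00214, and 0.655 with an estimated correlation). Not called were Hap1-type targets (7 up, 9 down), the TCA cycle (12 up, 5 down), sulfur and methionine (7 up, 12 down), fatty acid and sphingolipid synthesis (5 up, 19 down), and alcohol and acetate metabolism (9 up, 6 down). Single members of these moved far: the methylation gene OPI3 rose by 3.15 ± 0.11, INO1 by 4.25 and ADH5 by 4.08 ± 0.06, while the fatty acid desaturase gene OLE1 stood at -2.66 ± 0.29 and SAM1 at -2.62. Cell wall genes (11 up, 8 down), mating-type genes (11 up, 4 down) and genes variable between strains (12 up, 5 down, with CUP1-2 at 2.55, n = 2) were not called either. The glucose transport list (4 up, 4 down) had a median of 0.13 and a mean of -0.12, with the hexose transporter HXT1 at -2.91. The iron regulon (6 up, 8 down, adjusted p = 0.994) and pleiotropic drug response (2 up, 4 down, adjusted p = 0.745) were called in none of the 15 contrasts. In a fit of the ethanol arrays of the 3 strains alone with a replicate block the iron regulon was called in M22 minus DBY8268 (adjusted p = 0.0235) and in YPS163 minus M22 (0.00664).

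How do the wild strains respond? In M22, HSP12 rose by 8.29 ± 0.27 (SD, n = 3), RGI1 by 8.04 ± 0.73, the glucokinase gene GLK1 by 7.02 ± 0.38, GPM2 by 7.0 ± 0.59, PGM2 by 6.84 ± 0.19, TSL1 by 6.55 ± 0.15 and RTC3 by 6.53 ± 0.87. BSC1 stood at -3.70 ± 0.61, SSF1 at -3.42 ± 1.07, PRM7 at -3.40 and NOP15 at -3.39 ± 1.44. EDE1 rose by 1.39 ± 0.48, ELO1 by 1.05 ± 0.23, CTT1 by 4.72 ± 0.22, CYB2 by 5.21 ± 0.51 and the sodium pump gene ENA1 by 1.96 ± 0.03, and AQY2 stood at -1.33 ± 0.14. Of 5501 genes tested, 3412 changed, 1774 up and 1638 down. All 83 measured ribosome biogenesis genes fell (median -2.38, adjusted p = 0.0198 with an estimated correlation), and 126 ribosomal protein genes fell with 3 not passing (adjusted p = 0.621 with an estimated correlation). General stress genes had 47 up, 1 down and 7 not passing, with a median of 4.02 (adjusted p = 1e-06 with an estimated correlation), and trehalose and glycogen genes 18 up and 1 down (0.00457). Heat shock genes had 24 up, 1 down and 3 not passing (25 up adjusted over the list alone), with YDJ1 at -0.81 against the list (0.0356). The TCA cycle had 19 up, 1 down and 4 not passing, with CIT2 at 3.79 and CIT1 at 2.94, and adjusted p = 0.00343, 0.326 with an estimated correlation.

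In YPS163, RGI1 rose by 8.00 ± 0.16 (SD, n = 3), HSP26 by 7.70 ± 0.67, GLK1 by 7.26 ± 0.81, GPM2 by 7.20 ± 0.34, the hexokinase gene HXK1 by 6.45 ± 0.21 and PGM2 by 6.30 ± 0.36. The ferric reductase gene FRE4 stood at -4.31 ± 0.37, AQY2 at -4.07 ± 0.24, DBP2 at -3.95 ± 0.66, PRM7 at -3.78 and HXT1 at -3.51 ± 0.49. EDE1 rose by 1.08 ± 0.18 and CTT1 by 2.54 ± 0.29, and HSP30 stood at -1.04 ± 0.58. MET6 rose by 3.79 ± 0.62, MET17 by 3.61 ± 0.57 and LEU2 by 3.75. Of 5324 genes tested, 3222 changed, 1623 up and 1599 down. Ribosome biogenesis had all 83 measured genes down (median -2.22), general stress 44 up, 2 down and 8 not passing (3 down adjusted over the list alone), heat shock 25 up, 2 down and 2 not passing, and trehalose and glycogen 16 up, 1 down and 2 not passing. With an estimated correlation their adjusted p was 0.0198, 1.41e-05, 0.0198 and 0.00726. All 29 measured proteasome genes rose (1.27e-07, and 0.242 with an estimated correlation), and sulfur and methionine had 14 up, 3 down and 7 not passing (0.0141, and 0.539 with an estimated correlation). Amino acid biosynthesis, not called, had a median of -0.13 and a mean of 0.08. Among 5244 genes tested in DBY8268, M22 and YPS163, 1045 rose in all and 1205 fell in all, while 110 were called in opposite directions.

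**Figure D1:**
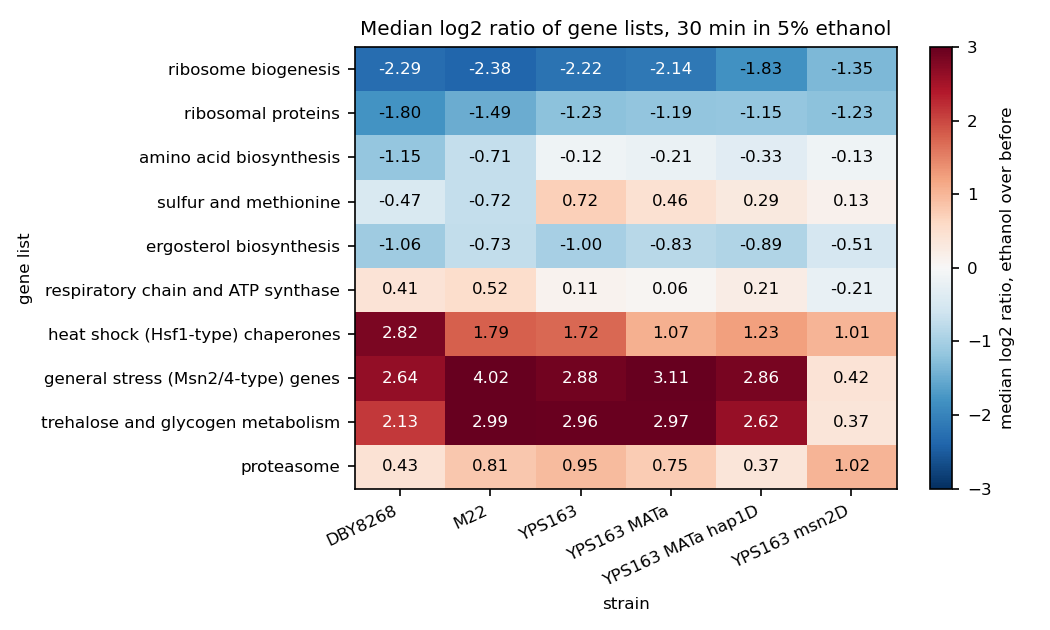
Median log2 ratio, ethanol over before, of 10 gene lists at 30 min in 6 strains (columns), with red for a rise and blue for a fall. The general stress median is 2.64 in DBY8268, 4.02 in M22 and 0.42 in msn2D.

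Which genes respond differently in M22 and DBY8268? The lactate dehydrogenase gene CYB2 had a higher log2 ratio in M22, by 3.17 ± 0.32 (standard error, adjusted p = 4.49e-06), as did HBT1 by 3.16 ± 0.39, FMP45 by 3.00 ± 0.59, CTT1 by 2.73 ± 0.32 (6.42e-06), the aconitase gene ACO1 by 2.63, MRH1 by 2.62, EXG1 by 2.57 and the arginase gene CAR1 by 2.53. HSP30 was lower in M22, at -4.49 ± 0.46 (8.06e-07), with HXT9 at -2.94 ± 0.83, BTN2 at -2.20 ± 0.41, FSH1 and MGA1 at -2.06 and TMA10 at -2.03. EDE1 differed by 1.34 ± 0.20 (0.00013), ELO1 by 1.5 ± 0.24 (0.000188), CYC1 by 1.43 ± 0.27, ENA1 by 2.08 ± 0.56 and AQY2 by -0.78 ± 0.24 (0.0331), while HSP12 at 0.85 did not pass. Of 5443 genes tested, 670 differed, 513 higher and 157 lower in M22, and 1368 did at an unadjusted p under 0.05. With arrays scaled to the same spread 103 differed, and in a fit of these arrays alone 184. The scaling also stretched the log-phase arrays, whose spread is shared with this contrast. Without the second DBY8268 array 437 genes differed, and in a fit of the ethanol arrays of the 3 strains alone with a replicate block HXT9 and HSP26 did not pass. That fit called more genes than the same arrays without the block. Heat shock genes had 13 lower and 15 not passing (15 lower adjusted over the list alone), with CUR1 at -1.96 ± 0.35 and HSP26 at -1.77 ± 0.43 (adjusted p = 4.96e-13, and 0.00692 with an estimated correlation). The phosphate regulon had 7 higher and 11 not passing (11 higher adjusted over the list alone), with VTC3 at 2.05 ± 0.18 (6.41e-07, and 0.000845 with an estimated correlation). In log phase this list was lower in M22 than in DBY8268, so its higher ratios need not be higher levels in ethanol. The TCA cycle had 10 higher and 14 not passing (13 higher adjusted over the list alone), with MDH2 at 2.11 and IDH1 at 1.82 (1.8e-06, and 0.0356 with an estimated correlation). General stress had 17 higher, 3 lower and 35 not passing (22 higher and 4 lower adjusted over the list alone), at adjusted p = 0.000104, and 0.358 with an estimated correlation. Trehalose and glycogen had 8 higher and 11 not passing, with TPS1 at 1.75 ± 0.30 (3.7e-05, and 0.263 with an estimated correlation), and Hap1-type targets 7 higher and 12 not passing (0.000939, and 0.239 with an estimated correlation).

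Which genes respond differently in YPS163 and DBY8268? The methionine synthase gene MET6 differed by 6.17 ± 0.30 (standard error, adjusted p = 5.86e-12), which is 72.2-fold, having risen in YPS163 and fallen in DBY8268. MET17 differed by 5.82 ± 0.31, LEU1 by 4.4 ± 0.21, SPL2 by 4.32 ± 0.52, OAC1 by 4.05 ± 0.18, PDH1 by 3.52 ± 0.49, DIC1 by 3.43 ± 0.24 and ZNF1 by 3.31 ± 0.80. HSP30 differed by -7.51 ± 0.46 (2.16e-10), YRO2 by -3.77 ± 0.89, AQY2 by -3.52 ± 0.24 (1.08e-09), ROQ1 by -3.45 ± 0.48, FRE4 by -3.16 ± 0.39 and BTN2 by -2.77 ± 0.40. Some of these genes already differed the other way in log phase, YPS163 over DBY8268. There MET6 stood at -3.28, -3.07 and -2.93 and AQY2 at 5.59, 4.78 and 4.96, while HSP30 stood at 0.07, -0.17 and -0.45. The 72.2-fold for MET6 is therefore not its gap in level during ethanol. EDE1 at 1.04 ± 0.20 (0.0013) and ELO1 at 0.76 ± 0.24 (0.0326) passed, and CTT1 at 0.55 (0.279), HSP12 at 0.20 (0.892) and CYC1 at 0.76 (0.0562) did not. Of 5300 genes tested, 850 differed, 554 higher and 296 lower in YPS163, against 151 under array scaling and 327 in a fit of these arrays alone. Without the second DBY8268 array 562 differed, and without YPS163 array 3 564 did. ZNF1 did not pass in the fit of the ethanol arrays of the 3 strains alone with a replicate block. That fit called more genes than the same arrays without the block. The phosphate regulon had 9 higher and 9 not passing (13 higher adjusted over the list alone), with PHO84 at 3.08 ± 0.28 and VTC3 at 2.97 ± 0.18 (adjusted p = 3.27e-08 with an estimated correlation). In log phase this list was lower in YPS163 than in DBY8268, so its higher ratios need not be higher levels in ethanol. Amino acid biosynthesis had 27 higher and 16 not passing (29 higher adjusted over the list alone), with BAT1 at 2.58 (0.00457 with an estimated correlation). Sulfur and methionine had 13 higher and 11 not passing (16 higher adjusted over the list alone), with STR3 at 2.99 and MMP1 at 2.79 (0.00474 with an estimated correlation). Heat shock had 13 lower and 15 not passing (14 lower adjusted over the list alone), with FES1 at -1.86 ± 0.20 (0.0192 with an estimated correlation). The respiratory chain had 12 lower, 1 higher and 28 not passing, with QCR8 at -1.10 (0.000183, and 0.505 with an estimated correlation). General stress, not called, had a median of 0.06 and a mean of -0.12.

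The differences of M22 and of YPS163 from DBY8268 shared 376 genes, among 655 and 842 in the 5244 genes tested in both. Independent lists of these sizes would share 53.3 higher and 8.1 lower genes, against 281 and 89 observed. Because both differences use the same DBY8268 arrays, independent lists are not what would be seen without an effect. The differences correlated at 0.62 across genes, which are not independent replicates, against 0.491 in 50 simulations with no effect and the same DBY8268 arrays. The covariance was 0.232 against 0.046 simulated. The simulations kept the shared DBY8268 arrays, so the excess over them is beyond what that sharing gave under independent noise. They did not carry the joint deviation of same-numbered arrays, whose part in the excess was not tested.

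Between the wild strains, MET6 differed by 5.75 ± 0.30 (standard error), MET17 by 4.99 ± 0.31, BOP2 by 3.28 ± 0.82, LEU1 by 3.28 ± 0.21, OAC1 by 3.22 ± 0.18 and MET5 by 2.76 ± 0.22, all higher in YPS163. HBT1 at -3.91 ± 0.39 (adjusted p = 4.36e-07), FMP45 at -3.53 ± 0.58, EXG1 at -3.14 ± 0.25, HSP30 at -3.02 ± 0.46, AQY2 at -2.73 ± 0.24 and CTT1 at -2.18 ± 0.32 were lower. Of 5254 genes tested, 332 differed, 113 higher and 219 lower in YPS163, against 62 under array scaling and 99 in a fit of these arrays alone. A replicate block on the ethanol arrays of the 3 strains alone gave more genes than those arrays without it. Sulfur and methionine had 14 higher and 10 not passing (15 higher adjusted over the list alone), with a median of 1.18 and adjusted p = 7.07e-07 with an estimated correlation. Amino acid biosynthesis had 15 higher and 28 not passing (0.0158 with an estimated correlation), the phosphate regulon 4 higher and 14 not passing (8 higher adjusted over the list alone, 0.0192), and mating-type genes 2 higher and 11 not passing, with NEJ1 at 2.62 ± 0.32 (0.0412). The other, STE2, did not pass in the limma fit of the ethanol arrays of the 3 strains alone with a replicate block (1.31, adjusted p = 0.109). The mating-type list is measured incompletely here. In YPS163, FAR1, RME1, STE3, STE4 and STE18 had no value, and AGA2, AXL1, FUS3, HO, MFA1 and MFA2 had 1. BAR1 had 1 value in M22, and none of these members was tested. General stress had 13 lower and 40 not passing (17 lower and 1 higher adjusted over the list alone), at adjusted p = 9.34e-08, and 0.124 with an estimated correlation.

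**Figure D2:**
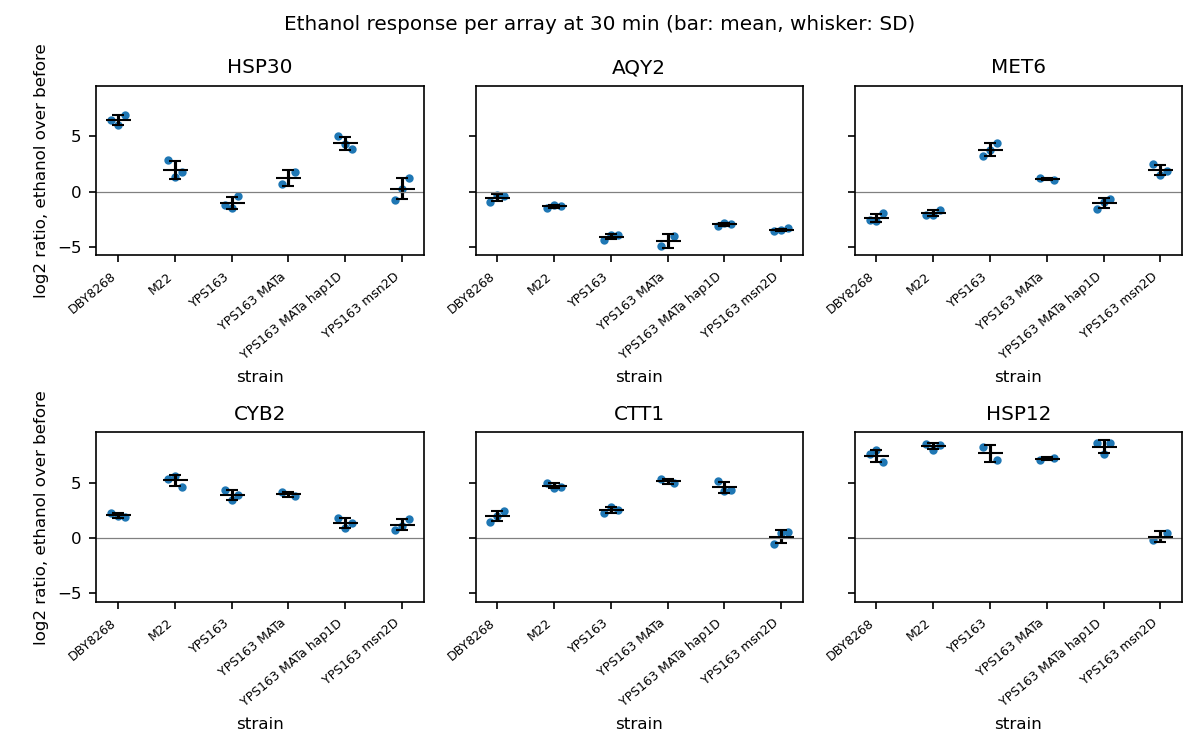
Log2 ratio, ethanol over before, of 6 genes on each array at 30 min in 6 strains, with a bar for the mean and a whisker for the SD. HSP30 has a mean of 6.47 in DBY8268 and -1.04 in YPS163, and MET6 of -2.39 and 3.79.

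Time courses of DBY8268, M22 and YPS163 had 1 array per time, with the first of the 3 arrays at 30 min, and were not tested. At 15, 30, 45 and 60 min HSP30 stood at 6.29, 6.46, 3.59 and 1.10 in DBY8268, at 4.46, 2.87, -0.44 and -1.38 in M22, and at 3.18, -1.22, -2.86 and -3.63 in YPS163. AQY2 in YPS163 went from -3.48 at 15 min to -5.56 at 60 min, and URA1 in DBY8268 from -0.99 to -3.85. HSP12 was still at 7.79 in DBY8268, 8.57 in M22 and 8.33 in YPS163 at 60 min. The heat shock median in DBY8268 was 2.29, 2.70, 1.23 and 0.81 at these times, and ended at 1.01 in M22 and 0.26 in YPS163, the last at the 83.8th percentile of random lists. General stress medians stayed between 2.25 and 3.32 in the 3 strains, at the 100th percentile at every time. Ribosome biogenesis medians lay between -1.33 and -2.32, at the 0th percentile at every time. The sulfur and methionine median went from -0.88 at 15 min to 1.02 at 60 min in M22 and from -0.27 to 0.93 in YPS163, and stood at -0.40 and -0.09 in DBY8268. With the mean of the 3 arrays at 30 min in place of the first, 25 of the 63 list medians at 30 min moved by more than the spread of the arrays, for example general stress in M22 from 3.15 to 3.81. The phosphate regulon median at 60 min was -0.97 in DBY8268, -0.02 in M22 and 1.46 in YPS163.

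**Figure D3:**
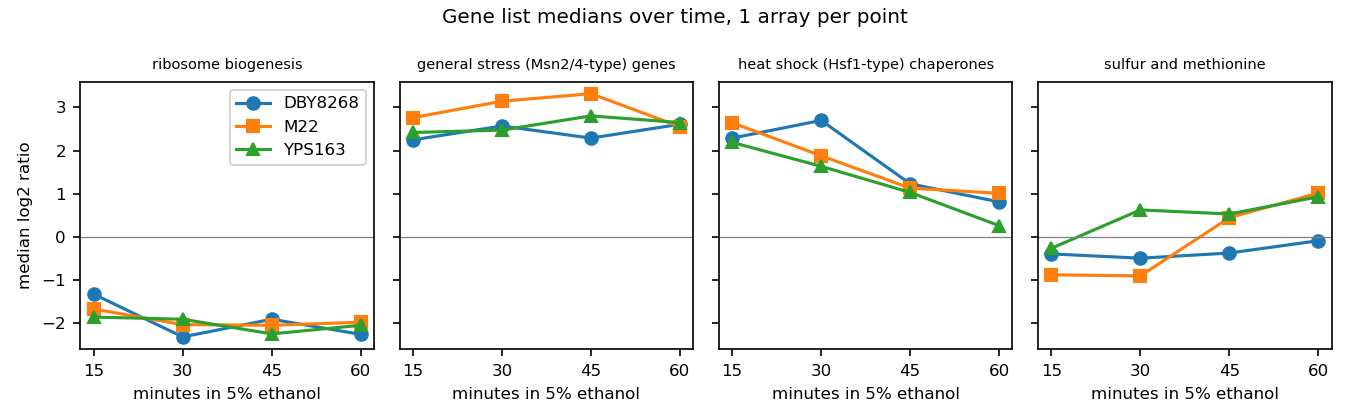
Median log2 ratio of 4 gene lists against minutes in 5% ethanol, with 1 array per point and no error bars. Heat shock medians at 60 min are 0.81 in DBY8268, 1.01 in M22 and 0.26 in YPS163.

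How do the strains differ without ethanol? In log phase M22 had more transcript than DBY8268 of the copper transporter gene CTR3, at 5.70 ± 0.32 (SD, n = 2), the mitochondrial genes ATP6 at 4.74 ± 0.78 (n = 3) and COX2 at 3.90 ± 0.76, the sulfate assimilation genes MET3 at 3.89 ± 0.24, MET10 at 3.12 ± 0.32, MET5 at 3.04 ± 0.48 and MET14 at 2.98 ± 0.26, and CYC1 at 2.37 ± 0.11. Lower were the asparaginase genes ASP3-4 at -7.21 ± 0.77 (n = 2) and ASP3-3 at -6.89 (n = 2), SPL2 at -5.33 ± 0.38, the phosphate transporter gene PHO89 at -5.07 ± 0.38, PRM5 at -4.98 ± 2.17, PLC1 at -4.30 ± 0.25 and ENA1 at -4.07 ± 0.27. Genes below -4 lacked a value on 25.1% of M22 ethanol spots, against 0.2% in DBY8268. Whether such genes are absent from M22, or present in fewer copies, was not examined, so these ratios need not mean lower transcription. HAP1 stood at -1.32 ± 0.29 (adjusted p = 2.22e-06), EDE1 at -0.44 (0.0226), ELO1 at -0.88 and AQY2 at 1.41 ± 0.32. Of 5107 genes tested, 1553 differed, 633 higher and 920 lower in M22, with 995 without the second array and 2344 under array scaling. The phosphate regulon had 16 lower and 1 not passing (16 lower and 1 higher adjusted over the list alone, adjusted p = 6.31e-08 with an estimated correlation). The respiratory chain had 32 higher, 1 lower and 6 not passing (33 higher and 2 lower adjusted over the list alone), with RIP1 at 2.62 ± 0.27 and COX5B at -2.71 (0.0356 with an estimated correlation). Hap1-type targets had 12 higher, 1 lower and 5 not passing (0.00732 with an estimated correlation), and sulfur and methionine 16 higher, 1 lower and 7 not passing (17 higher adjusted over the list alone, 0.00342 with an estimated correlation). Genes variable between strains had 20 lower, 4 higher and 7 not passing (21 lower and 5 higher adjusted over the list alone), at adjusted p = 0.00205, and 0.404 with an estimated correlation.

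In log phase YPS163 had more ATP6 than DBY8268, at 5.18 ± 0.16 (SD, n = 3), AQY2 at 5.11 ± 0.43, FRE4 at 4.71 ± 0.66, VAR1 at 3.70 ± 0.33, COX1 at 3.45 ± 0.28, CYC1 at 3.22 ± 0.35 and RIP1 at 2.65 ± 0.25. Lower were ASP3-3 at -6.43 (n = 2), ASP3-4 at -6.20 (n = 2), the flavohaemoglobin gene YHB1 at -5.07 ± 0.92, TIP1 at -4.94 ± 0.71, MET17 at -3.57 ± 0.62 and MET6 at -3.09 ± 0.18. HAP1 stood at -1.10 ± 0.27 (adjusted p = 3.3e-05), MGA2 at -0.88 and ENA1 at -2.91 ± 2.01. Of 5532 genes tested, 1266 differed, 475 higher and 791 lower in YPS163, with 743 without the first array and 191 in a fit of these arrays alone. The respiratory chain had 34 higher, 1 lower and 5 not passing (36 higher adjusted over the list alone), with a median of 1.05 (0.00457 with an estimated correlation). Hap1-type targets had 10 higher, 2 lower and 5 not passing (11 higher adjusted over the list alone, 0.00863 with an estimated correlation), and the phosphate regulon 14 lower and 4 not passing (14 lower and 1 higher adjusted over the list alone, 3.14e-07 with an estimated correlation). Ergosterol biosynthesis had 19 higher, 3 lower and 5 not passing (20 higher adjusted over the list alone, adjusted p = 4.53e-07, and 0.231 with an estimated correlation), and amino acid biosynthesis 21 lower, 2 higher and 19 not passing (0.00113, and 0.621 with an estimated correlation). A level set against DBY8268 on these arrays, in M22 as in YPS163, also carries any difference in how well the strains' sequences match the probes. It carries any difference in the copies of a gene too, its absence included.

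What does loss of HAP1, a haem-responsive activator, change? HAP1 had no value on the 3 hap1D ethanol arrays, and in log phase it stood at -3.47 ± 0.61 (SD, n = 2) in hap1D over YPS163 MATa. The direction of these log-phase ratios was chosen from HAP1 itself, so the sign of that value is not a result. In ethanol it was measured at -0.48 in DBY8268, -0.64 in M22, -0.65 in YPS163, -0.14 in YPS163 MATa and -0.26 in msn2D. In log phase the cytochrome c gene CYC1 stood at -4.95 ± 0.39 (n = 3, adjusted p = 3.99e-13) in hap1D, a fall of 30.8-fold, with the cytochrome bc1 genes RIP1 at -2.28 ± 0.20 and CYT1 at -1.92, RSB1 at -2.15, TPP1 at -1.69, the haem oxygenase gene HMX1 at -1.63 and HMG1 at -1.60. The cell wall genes DAN1 at 5.89 ± 1.05, DAN4 at 4.16 ± 1.32, PAU14 at 2.35, PAU1 at 2.21 and TIP1 at 2.19 were higher, as were PGU1 at 2.12 and FET4 at 1.59. The repressor gene ROX1 stood at -1.05, ELO1 at -1.07, AQY2 at -0.66 (0.0334) and the ergosterol genes ERG13 at -1.50 and ERG11 at 1.08. Of 6059 genes tested, 181 differed, 80 higher and 101 lower in hap1D, and without array 1, 2 or 3 the counts were 84, 115 and 94. Array scaling gave 1658 and a fit of these arrays alone 28. With the column of YPS163 MATa ethanol array 3 as deposited, which enters this result through the shared spread, 89 differed, and with it moved 166. The respiratory chain had 31 lower and 11 not passing (38 lower adjusted over the list alone), with a median of -0.83 and adjusted p = 9.3e-13 with an estimated correlation. Hap1-type targets had 11 lower, 1 higher and 8 not passing (12 lower and 2 higher adjusted over the list alone), with adjusted p = 1.25e-12 with an estimated correlation. The cell wall list was called upward (adjusted p = 0.00141, and 0.675 with an estimated correlation) with 3 higher and 30 not passing, a mean of 0.34 and a median of -0.02. Ergosterol biosynthesis (5 higher, 7 lower) and fatty acid synthesis (4 lower, 24 not passing) were not called.

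In ethanol, YPS163 MATa raised RGI1 by 8.89 ± 0.24 (SD, n = 2), HSP12 by 7.16 ± 0.13, HSP26 by 6.77 ± 0.41, HXK1 by 6.59 ± 0.01 and CTT1 by 5.12 ± 0.24, with AQY2 at -4.44 ± 0.62 and FRE4 at -4.17 ± 0.35. It had 2839 changed genes of 5444 tested, 1332 up and 1507 down, against 2582 with the column of its array 3 as deposited, 3262 with the column moved and 1796 without the first array. hap1D raised RGI1 by 9.67 ± 0.05 (n = 3), HSP12 by 8.25 ± 0.59, PGM2 by 7.33 ± 0.20 and CTT1 by 4.58 ± 0.50, with TOD6 at -3.04 ± 0.54 and AQY2 at -2.97 ± 0.11, and had 3305 changed genes of 6056 tested. General stress had 48 up, 1 down and 5 not passing in YPS163 MATa (adjusted p = 1.55e-06 with an estimated correlation) and 54 up, 1 down and 5 not passing in hap1D (6.05e-07). Ribosome biogenesis had 86 of 86 down in YPS163 MATa (0.0223 with an estimated correlation) and 89 down and 1 not passing in hap1D (0.0356).

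The responses of hap1D and YPS163 MATa differed in 5 genes of 5397 tested, and in 400 at an unadjusted p under 0.05. HSP30 was higher in hap1D by 3.16 ± 0.51 (standard error, adjusted p = 0.00832), AQY2 by 1.47 ± 0.26 (0.0203) and CPA1 by 1.33 ± 0.18 (0.0203). CYB2 at -2.59 ± 0.36 and MET6 at -2.21 ± 0.34 (both 0.00542) were lower. AQY2 fell in both strains, by less in hap1D. CTT1 at -0.54 (0.836), HSP12 at 1.09 (0.831) and CYC1 at 0.45 did not pass. The count was 7 with the column of YPS163 MATa array 3 as deposited, 19 with it moved, 0 in a fit of the family's ethanol arrays alone with or without a replicate block, 0 under array scaling and in a fit of these arrays alone, 0 without the first YPS163 MATa array, 10 without the second, and 16, 8 and 3 without hap1D arrays 1, 2 and 3. Proteasome genes had a median of -0.35 with 30 not passing (1 lower adjusted over the list alone, adjusted p = 7.18e-13, and 0.06 with an estimated correlation). Ribosome biogenesis had 86 not passing and a median of 0.36 (called upward, 3.61e-10, and 0.505 with an estimated correlation). The direction of the camera test turned without the first YPS163 MATa array, where the median was still above 0 at 0.05, and with the column as deposited, at a median of -0.30. In this difference sulfur and methionine had 20 not passing (3 lower adjusted over the list alone, 0.000344, and 0.232 with an estimated correlation). Hap1-type targets, not called, had 1 lower and 17 not passing, with a median of 0.12 and a mean of -0.13.

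What does the stress activator gene MSN2 contribute to the response? MSN2 had no value on the 3 msn2D ethanol arrays, and stood at 0.51 in DBY8268, 0.53 in M22, 0.40 in YPS163, 0.17 in YPS163 MATa and -0.06 in hap1D. In msn2D, GLK1 rose by 5.59 ± 0.25 (SD, n = 3), GPM2 by 4.78 ± 0.68, the aromatic amino acid catabolism genes ARO10 by 4.25 ± 0.51 and ARO9 by 3.94 ± 0.48, SLX8 by 4.19 ± 0.23, SSA4 by 3.98 ± 0.40, INO1 by 3.77 ± 0.60 and IES5 by 3.73 ± 0.17. AQY2 at -3.44 ± 0.10, HXT6 at -3.05 ± 0.27, HXT4 at -2.74, KAP123 at -2.71 and OLE1 at -2.70 fell. HSP12 at 0.13 (n = 2, adjusted p = 0.886), CTT1 at 0.13 ± 0.60 (0.693) and CYC7 at -0.44 (0.187) did not pass. Of 6138 genes tested, 2664 changed, 1288 up and 1376 down. General stress had 25 up, 1 down and 33 not passing, with a median of 0.42 (7.95e-09, and 0.0991 with an estimated correlation). Heat shock had 24 up and 8 not passing, with HSP42 at 3.48 ± 0.86 and KAR2 at 2.55 ± 0.12 (0.0203 with an estimated correlation), and the proteasome 30 up and 2 not passing (31 up adjusted over the list alone), with PRE3 at 1.40 ± 0.06 (0.0192 with an estimated correlation). Glucose transport had 13 down and 10 not passing (0.00527, and 0.683 with an estimated correlation).

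Against YPS163 MATa, msn2D had lower log2 ratios for HSP12 at -7.03 ± 0.78 (standard error, adjusted p = 6.01e-05), DAD3 at -6.33 ± 0.33, the phosphoglucomutase gene PGM2 at -6.21 ± 0.33 (1.12e-09), DDR2 at -6.05 ± 0.79, RGI1 at -5.78 ± 0.84, HXK1 at -5.72 ± 0.43, HXT6, which rose in YPS163 MATa and fell in msn2D, at -5.42 ± 0.95 and CTT1 at -4.99 ± 0.36 (1.26e-08). Differences above 0 were TOD6 at 2.64 ± 0.43 (0.000529), TRF5 at 2.38 ± 0.42, ENP2 at 2.37 ± 0.45, FAR1 at 2.20 ± 0.23, TEC1 at 2.17 ± 0.40 and AQY2 at 1.00 ± 0.26 (0.0214). AQY2 turned to -0.08 under array scaling and to -0.35 with the column as deposited. Of 5394 genes tested, 472 differed, 236 in each direction. The count was 144 with the column of YPS163 MATa array 3 as deposited, 439 with it moved, 135 under array scaling, 87 without the first YPS163 MATa array, and 263, 284 and 280 without msn2D arrays 1, 2 and 3. General stress had 31 lower and 22 not passing (37 lower adjusted over the list alone), with a median of -1.63 and adjusted p = 1.66e-09 with an estimated correlation. Trehalose and glycogen had 12 lower and 6 not passing (13 lower adjusted over the list alone), with TSL1 at -4.57 (7e-07 with an estimated correlation). Mating-type genes had 5 higher and 17 not passing (8 higher adjusted over the list alone), with GPA1 at 1.70 and SST2 at 1.66 (0.0292 with an estimated correlation). The median of that list went from 0.65 to -0.09 with only genes present on all arrays and to 0.18 without msn2D array 3, and the list was no longer called in either. Ribosome biogenesis had 25 higher and 60 not passing (48 higher adjusted over the list alone, adjusted p = 2.24e-16, and 0.299 with an estimated correlation). Glucose transport had 7 lower, 1 higher and 12 not passing (11 lower adjusted over the list alone), with HXT11 at -4.33 (3.75e-07, and 0.239 with an estimated correlation). Heat shock, not called, had 3 lower, 1 higher and 24 not passing, a median of 0.15 and a mean of -0.28. The labels give msn2D a YPS163 title and a MATa genotype, and against YPS163 instead 906 genes differed. There TEC1 turned to -1.37, GPA1 to -0.64 and the mating-type median to -0.66.

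**Figure D4:**
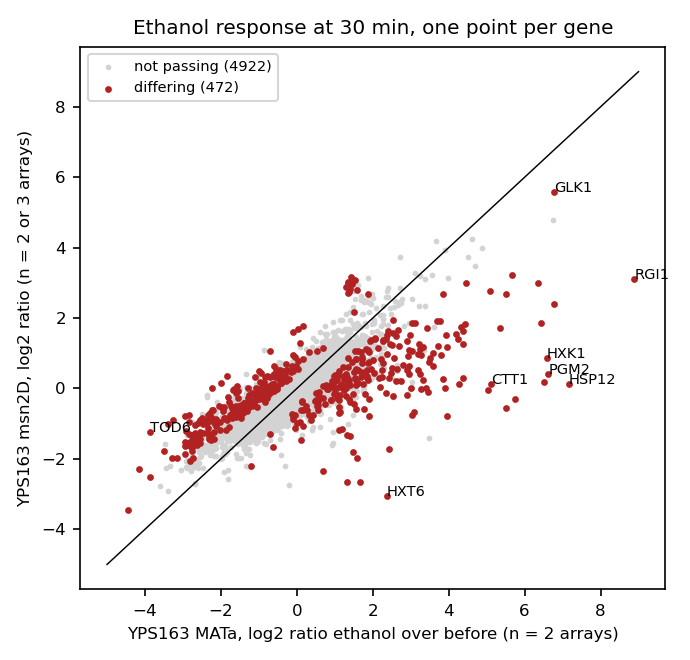
Log2 ratio after 30 min of ethanol in msn2D (mean of up to 3 arrays) against YPS163 MATa (mean of 2), 1 point per gene, with the line of equal response. The 472 differing genes are red, among them HSP12 at 0.13 in msn2D (n = 2) and 7.16 in YPS163 MATa, and 4922 are grey.

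YPS163 MATa and YPS163 share a background but not a label of mating type, and their responses differed in 35 genes of 4867 tested, 10 higher and 25 lower in YPS163 MATa. Their same-numbered arrays 1 and 2 correlated at -0.211 and -0.106, so the numbers do not pair them. The YPS163 MATa arrays used lacked 8.09% and 8.96% of values, and the YPS163 arrays 15.42% to 18.17%. Strain and family of arrays therefore cannot be told apart here. HXT3 at 2.81 ± 0.51 (standard error, adjusted p = 0.00497), CTT1 at 2.58 ± 0.36 (0.000309) and HSP30 at 2.25 ± 0.51 (0.0353) were higher. TEC1 at -3.54 ± 0.40 (2.21e-05), MET17 at -3.15 ± 0.34, FMP23 at -3.15 ± 0.50, the pheromone receptor gene STE2 at -2.85 ± 0.30, MET6 at -2.64 ± 0.34, DDR48 at -2.52 ± 0.22 and GPA1 at -2.34 were lower. With the column of YPS163 MATa array 3 as deposited 55 genes differed, with it moved 73, without the second YPS163 MATa array 14, under array scaling 5 and in a fit of these arrays alone 3. Mating-type genes had 4 lower and 8 not passing (7 lower adjusted over the list alone), with a median of -1.30 and adjusted p = 4.43e-13 with an estimated correlation. The list is measured incompletely in YPS163. There FAR1, RME1, STE3, STE4 and STE18 had no value, and AGA2, AXL1, FUS3, HO, MFA1 and MFA2 had 1. Those members were not tested, and BAR1 entered with 0.26 ± 3.22 (SD, n = 2) in YPS163. Sulfur and methionine had 3 lower and 16 not passing (0.0192 with an estimated correlation), and the phosphate regulon 1 lower and 16 not passing (4 lower adjusted over the list alone), with PHO84 at -1.71 (0.0198 with an estimated correlation).

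**Figure D5:**
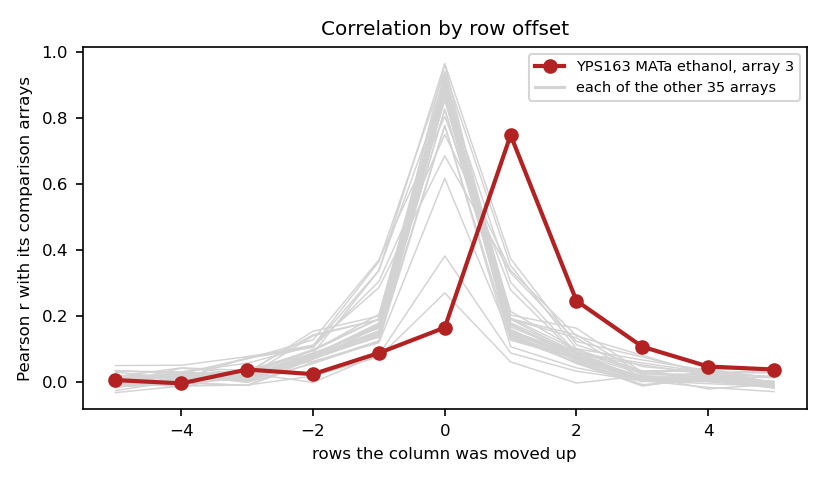
Pearson r of each array with its comparison arrays, across genes, against the number of positions its column was moved up. Ethanol array 3 of YPS163 MATa (red) reaches 0.747 at 1 position from 0.164 at 0, and the other 35 arrays (grey) are best at 0.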

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

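The tests of the displaced column, of the mating state of msn2D and of Hap1-dependent genes were chosen after the result was seen, while the splits of the arrays were planned.

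Differences between the ethanol responses of strains were tested directly, and each pair had genes that passed. M22 and DBY8268 differed in 670 genes and YPS163 and DBY8268 in 850. YPS163 and M22 differed in 332, hap1D and YPS163 MATa in 5, msn2D and YPS163 MATa in 472, and YPS163 MATa and YPS163 in 35. Groups of 3 make 10 splits of the arrays, and a group of 2 against 3 makes as many, too few for a share under 0.05. The highest count of another split, in the order given, was 6, 5, 595, 150, 5 and 13, and 1, 1, 2, 3, 1 and 1 splits reached the real count, the real one included. For YPS163 and M22 the split with 595 set arrays 1 and 2 of M22 with array 1 of YPS163 against the rest, which points to a structure of the arrays other than strain, and with a replicate block the real split gave 303. That split parts 1 of the 3 pairs of same-numbered arrays, and among splits that part all 3 pairs the highest other count was 0 there, 1 for M22 and DBY8268 and 0 for YPS163 and DBY8268. For hap1D and YPS163 MATa the split with 150 set the arrays numbered 1 against the others, so replicate number parted those arrays more than genotype did, and the family's ethanol arrays alone gave 0 for the real split with or without a replicate block.

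Some of the named genes that passed also moved in opposite directions in the groups compared. In M22 minus DBY8268 these were ACO1 at 2.63 (mean responses 0.64 and -1.99), MRH1 at 2.62 (1.72 and -0.90), EXG1 at 2.57 (2.00 and -0.57), CAR1 at 2.53 (1.73 and -0.80), ELO1 at 1.5 (1.05 and -0.45), CYC1 at 1.43 (0.74 and -0.69), DAL1 at -2.18 (-1.41 and 0.77) and HXT17 at -2.1 (-0.97 and 1.14). In YPS163 minus DBY8268 they were MET6 at 6.17 (3.79 and -2.39), MET17 at 5.82 (3.61 and -2.20), LEU1 at 4.4 (2.52 and -1.88), OAC1 at 4.05 (2.73 and -1.32) and HSP30 at -7.51 (-1.04 and 6.47). In YPS163 minus M22 they were MET6 at 5.75, MET17 at 4.99, LEU1 at 3.28 and OAC1 at 3.22, with M22 at -1.96, -1.38, -0.76 and -0.49, and MET5 at 2.76 (0.65 and -2.11), NEJ1 at 2.62 (2.00 and -0.62), EXG1 at -3.14 (-1.14 and 2.00) and HSP30 at -3.02 (-1.04 and 1.98). In hap1D minus YPS163 MATa, MET6 stood at -2.2 (-1.06 and 1.15), and in msn2D minus YPS163 MATa, HXT6 at -5.42 (-3.05 and 2.36). In YPS163 MATa minus YPS163 they were HSP30 at 2.25 (1.21 and -1.04), LAF1 at 1.2 (0.61 and -0.59), TLD1 at 1.15 (0.84 and -0.30), TEC1 at -3.54 (-2 and 1.53) and STE2 at -2.85 (-1.81 and 1.04).

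Ethanol array 3 of YPS163 MATa stood apart from arrays 1 and 2 of its group. A displacement of the column by 1 position predicts that blocks all along the table correlate best after 1 step, and 32 of 32 blocks did. With a poor hybridisation no offset would restore the correlation, and the correlation with arrays 1 and 2 rose from 0.164 to 0.747. That rise cannot tell against another ethanol-treated sample in a displaced column. The single time-course arrays correlated at 0.776 to 0.923 with the mean of other ethanol arrays across strains. A displaced column may therefore explain most of the gap. After the move 165 of 183 strong genes, not all, came within 1.5 of their mean on the YPS163 MATa and hap1D ethanol arrays. No biological explanation was tested.

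In msn2D against YPS163 MATa, 31 general stress genes had lower log2 ratios, and 5 mating-type genes higher ones, in a list with 10 genes down and 1 up in YPS163 MATa (median -0.68) and 1 down and 3 up in msn2D (-0.15). If mating state or ploidy in place of MSN2 lowered the general stress response, that response would equal the one of YPS163. The median of the list in msn2D minus YPS163 was -1.667, which argues against that explanation as the whole cause. That comparison sets arrays of different families against each other, so it also carries any difference between the families. For the mating-type genes, a mating state of msn2D unlike that of YPS163 MATa predicts that their differences vanish or turn against YPS163. Of the 5 called genes 3 could be tested against YPS163, 0 passed in the same direction and 1 passed in the opposite one, and a limit of 5 genes for a verdict was set after this outcome, so the test decides nothing. Part of the 472 genes may still reflect mating state, and 906 genes differed with YPS163 as the reference.

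Genes lower in hap1D than in YPS163 MATa in log phase tended to be higher in the wild strains than in DBY8268. Of 100 such genes, HAP1 itself left out, 76 of 90 measured in M22 (84.4%) and 79 of 93 in YPS163 (84.9%) lay above 0, above the central 95% of random gene sets, which ended at 57.8% and 60.2%. Random sets drew genes independently, while this set includes respiratory chain genes, which fell together in hap1D. That limit therefore does not measure chance for genes that move together. A probe mismatch to wild-strain sequences would put these genes below 0, and the lower of the medians was 0.64. Because the pattern is itself that most of these genes lie above 0, that median was bound to be positive. It is no separate test of a mismatch, and it does not show whether single genes mismatch. Lower Hap1 activity in DBY8268 is a candidate explanation that these values leave open, with 55 of 71 genes higher in hap1D lying below 0 in M22 and 54 of 72 in YPS163. HAP1 transcript itself was lower in the wild strains, at -1.32 and -1.10, other differences between the strain backgrounds remain untested, and the readings here would turn if the direction taken for the wild-strain or for the hap1D ratios were wrong.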

How the results depend on the processing

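The treatments of the displaced YPS163 MATa column and the other references for msn2D were chosen after the results were seen; the other settings were planned. Array centring, a dye term and robust empirical Bayes moved none of the 15 counts by over 1.5 times, and where a count moved the cause was not tested except as stated. Array scaling stretched the narrower log-phase arrays relative to the ethanol arrays, so its counts do not measure the ethanol contrasts alone. With arrays scaled to the same spread, M22 minus DBY8268 had 103 genes, YPS163 minus DBY8268 151, YPS163 minus M22 62, M22 over DBY8268 in log phase 2344, hap1D minus YPS163 MATa 0, msn2D minus YPS163 MATa 135, hap1D over YPS163 MATa in log phase 1658 and YPS163 MATa minus YPS163 5; the median of ribosome biogenesis in M22 minus DBY8268 turned to 0.105 and AQY2 in msn2D minus YPS163 MATa to -0.08. With only genes present on all arrays, which leaves fewer genes, ethanol changed 1992 in DBY8268, 2017 in M22, 1943 in YPS163, 1695 in YPS163 MATa, 1841 in hap1D and 1590 in msn2D; YPS163 minus DBY8268 had 558, YPS163 minus M22 195, msn2D minus YPS163 MATa 305, YPS163 MATa minus YPS163 14, and log phase 969 (M22), 768 (YPS163) and 105 (hap1D). In a fit of each contrast's arrays alone, with fewer arrays for the spread, M22 minus DBY8268 had 184, YPS163 minus DBY8268 327, YPS163 minus M22 99, hap1D minus YPS163 MATa 0, YPS163 MATa minus YPS163 3, YPS163 in log phase 191 and hap1D in log phase 28. At an adjusted p under 0.01, stricter by construction, M22 minus DBY8268 had 349, YPS163 minus DBY8268 415, YPS163 minus M22 166, hap1D minus YPS163 MATa 3, msn2D minus YPS163 MATa 170, YPS163 MATa minus YPS163 20, and log phase 1026 (M22), 746 (YPS163) and 98 (hap1D). With a minimum change of 1.5-fold, also stricter, ethanol changed 1540 in DBY8268, 1629 in M22, 1460 in YPS163, 1147 in YPS163 MATa, 1252 in hap1D and 759 in msn2D; M22 minus DBY8268 had 94, YPS163 minus DBY8268 136, YPS163 minus M22 85, hap1D minus YPS163 MATa 0, msn2D minus YPS163 MATa 69, YPS163 MATa minus YPS163 10, and log phase 369 (M22), 317 (YPS163) and 28 (hap1D). There the direction of the camera test turned for the proteasome in M22 minus DBY8268 and in YPS163 MATa minus YPS163, whose medians stayed at 0.347 and -0.252. With the displaced column as deposited, M22 minus DBY8268 had 325, YPS163 minus DBY8268 425, YPS163 minus M22 165, msn2D minus YPS163 MATa 144, hap1D in log phase 89 and YPS163 MATa minus YPS163 55; AQY2 in msn2D minus YPS163 MATa turned to -0.35, in hap1D minus YPS163 MATa ribosome biogenesis to -0.303 and general stress to 0.707, and general stress in YPS163 MATa minus YPS163 to -0.687. With the column moved, hap1D minus YPS163 MATa had 19 and YPS163 MATa minus YPS163 73, and the direction of the general stress test turned in hap1D minus YPS163 MATa, at a median of 0.124. A fit of a family's ethanol arrays alone with a replicate block gave 0 for hap1D minus YPS163 MATa, 677 for M22 minus DBY8268, 1015 for YPS163 minus DBY8268, 303 for YPS163 minus M22 and 342 for msn2D minus YPS163 MATa; the same ethanol arrays without the block gave 0, 254, 368, 148 and 523. In the paired strains that fit, which changes the arrays as well as the block, ended 11 calls of named genes and that of the proteasome list in M22 minus DBY8268. It gained ENA1 and the iron regulon in YPS163 minus M22, and ribosomal proteins, ergosterol biosynthesis and the iron regulon in M22 minus DBY8268. No paired analysis was possible for YPS163 MATa minus YPS163 because the numbers do not pair across the families. Against YPS163, msn2D differed in 906 genes and the differences of TEC1 turned to -1.37, GPA1 to -0.64, FLO10 to -0.62 and the mating-type median to -0.655; against the mean of YPS163 MATa and YPS163 931 genes differed. Leaving out 1 array at a time gave 2809 to 3064 genes for ethanol in DBY8268, 2969 to 3045 in M22, 2740 to 2850 in YPS163, 1796 to 2306 in YPS163 MATa, 2543 to 2831 in hap1D and 2008 to 2209 in msn2D; 437 to 782 for M22 minus DBY8268, 562 to 810 for YPS163 minus DBY8268, 230 to 325 for YPS163 minus M22, 0 to 16 for hap1D minus YPS163 MATa, 87 to 442 for msn2D minus YPS163 MATa and 14 to 42 for YPS163 MATa minus YPS163; and in log phase 995 to 1075 for M22, 743 to 1286 for YPS163 and 84 to 115 for hap1D. The lone YPS163 MATa array then left is assumed to vary like the other groups. Without the first YPS163 MATa array, medians in hap1D minus YPS163 MATa were 0.05 for ribosome biogenesis and 0.107 for general stress, and without the first YPS163 array glucose transport in YPS163 MATa minus YPS163 had -0.165, each with the test's direction turned; the other ends of their ranges over arrays left out were 0.612, -0.413 and 0.3. Among 695 values of named genes, 87 fell below the threshold at 0.01, 168 with the minimum change, 135 with scaling and 7 with centring; among 315 list tests, 21, 40, 10 and 2 did. The overlap of the differences of M22 and YPS163 from DBY8268 was 178 genes at an adjusted p under 0.01. No intensities were used, so signal over background was not examined. The probe alternative did not apply, with 1 value per open reading frame.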

Other observations

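The gene sets described here were chosen after their values were seen, and no explanation was tested for them.

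The table holds 1073 open reading frames without a standard gene name, and some of these lay far below DBY8268 in log phase in the wild strains, 66 under -4 in M22 and 75 in YPS163, of which 65 were shared. In ethanol, members of this shared set rose in each of the 6 strains: 21 of 65 tested in DBY8268 with a median of 0.38, 41 of 53 in M22 with a median of 2.94, 43 of 46 in YPS163 with 2.13, 35 of 47 in YPS163 MATa with 1.41, 48 of 64 in hap1D with 1.18 and 51 of 64 in msn2D with 1.91. The other open reading frames without a name had medians of 0.09 in DBY8268 (210 up, 154 down), 0.02 in M22 (192 up, 167 down), 0.06 in YPS163 (172 up, 144 down), -0.002 in YPS163 MATa (153 up, 144 down), 0.16 in hap1D (224 up, 146 down) and -0.16 in msn2D (124 up, 154 down). The log2 ratio was higher in M22 than in DBY8268 for 36 of 53 of the set, and in YPS163 for 34 of 46. Of the other open reading frames without a name, 49 of 637 were higher and 24 lower in M22, and 39 of 556 higher and 35 lower in YPS163. Between YPS163 and M22, 20 of 44 of the set were lower in YPS163 and 1 higher. Because the set was chosen for low unstressed levels in the wild strains, larger ratios there may be partly built in. The sequences of its members were not compared, so these counts need not be of independent genes. Between msn2D and YPS163 MATa 11 of 47 differed, all higher in msn2D. Named or not, the 77 genes below -4 in M22 lacked a value on 25.1% of M22 ethanol spots, so the set is measured incompletely there.

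MSN4, the paralogue of MSN2, had higher values at 45 and 60 min in YPS163 than in the other strains, with 1 array per time apart from 30 min. In YPS163 it stood at 0.49 at 15 min, 0.35 ± 0.19 (SD, n = 3) at 30 min, 2.40 at 45 min and 2.44 at 60 min. In DBY8268 the values were 0.42, 0.70, 1.14 and 1.12, and in M22 0.19, 0.54, 0.91 and 0.56. The differences between the strains over time were not tested.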
